A study of Mus musculus with 6 samples.

How the data were processed

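Poly(A)-selected RNA of mouse intestinal epithelial cells was sequenced in 6 libraries, 3 from wild-type mice and 3 labelled Git2-knockout. The titles speak of isolated epithelial cells, and the series' design text calls the samples enteroids (epithelial organoids grown from crypts) of mice aged 12 days. Groups and replicate numbers were taken from the sample titles. The genotype field of the same samples says knockdown where the titles say knockout. Per the labels' protocols, libraries were made from total RNA by capture on oligo(dT), fragmentation and cDNA synthesis. The submitters' processing notes name HISAT, Bowtie2, RSEM and the GRCm39 genome build, with no versions, and strand setting and annotation are not given in the sources used here.

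The values came as 1 table of 18159 genes, each with a symbol and an NCBI gene number. Per the file headers it holds read counts, which were taken as estimated counts because 58.9% to 69.2% of the values per library were not whole numbers. FPKM values, which scale reads by transcript length and library total, are also deposited for each library, per the file headers. TPM values are deposited in the same way, per the file headers, and sum to 1000000 in each library. The authors' group averages in the table equal the means of the 3 libraries and were not used. All 18159 genes had a count above 0 in at least 1 library. Of the gene numbers, 99.3% matched the RefSeq gene table of the GRCm38 assembly, and 99.0% of the matched genes were protein coding. That table served only for chromosome numbers and for which genes lie near each other, and no coordinates are given because the builds differ.

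Total estimated counts per library ran from 16284414 to 19106581. Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 13558 of them, libraries were scaled by TMM, and groups were compared with the robust quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, no covariates). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are CPM, reads per 1000000 reads of a library, scaled by the TMM factors, as mean ± SD over 3 libraries. Nothing in the labels says that the libraries of a group come from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Chi-square statistics per degree of freedom between replicates ran from 1.59 to 6.79, so replicates differed by more than counting noise and each was counted. Between the groups the statistic ran from 28.2 to 40.2.

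The design, the tests, 40 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Git2, the 10 largest rises and 10 largest falls, and the 5 rises and 5 falls with the smallest p, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups. It adds up to 4 called members per list with the smallest p and, for some lists, up to 3 with the highest expression. Predicted or unnamed gene models, LOC symbols included, were counted but not named, and a few genes that the rule names are not reported here. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and not whether they differ from other genes, were run beside it. With an estimated correlation camera also uses far fewer degrees of freedom, those left by the 6 libraries. Its p can therefore rise whatever the correlation. The list of mitochondrially encoded mRNAs had 0 members in the table, and the list of sex-linked genes had 4 tested members, too few for camera. Genes within 10 Mb of Git2 were compared with all others by Fisher's exact test.

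Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, non-robust fits, the replicate number as a block, leaving out each library, and windows of 5 and 20 Mb. A further 5 alternatives were chosen after seeing the data: removal of a transcript length trend, of a GC trend and of both by a loess curve per library (span 0.5), limma-trend on log2(TPM + 1), and a test against a 1.5-fold change. Transcript length was the length implied by the estimated counts and FPKM where FPKM was at least 0.5 and covered 93.1% of tested genes. GC content came from GENCODE mouse transcripts of the GRCm38 assembly and covered 97.9%.

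The steps were tested on simulated data. In a simulated comparison of Git2-knockout with wild-type libraries on 13421 genes, with 50 genes changed at each size, edgeR recovered 54% of 1.25-fold, 74% of 1.5-fold, 92% of 2-fold and 100% of 4-fold changes, with 14 false calls. That simulation held no trend with transcript length. A second one on 13394 genes added such a trend, stronger than that of the data (Spearman 0.89 against 0.49). There edgeR made 5069 false calls, and 9 once the trend was removed. The 14 false calls are thus no error rate for the real comparison. Reads of near-identical genes can be divided wrongly by any counting method. Values of the clustered zinc finger genes Zfp979, Zfp990 and Zfp982, of Eno1b, Tuba1a, the globins, the defensins and Reg3b and Reg3g are therefore uncertain.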

Results

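Gene expression was measured in intestinal epithelial cells of mice aged 12 days, 3 libraries from wild-type animals and 3 labelled Git2-knockout. Wild-type libraries held 18753649, 18974161 and 19106581 estimated reads, and the libraries labelled Git2-knockout held 16284414, 16822399 and 16837158. The 10 most abundant genes took 7.0% to 7.7% of the reads of a library. On a multidimensional scaling of the libraries the groups separated along the leading dimension, which held 57.9% of the variation. The series title concerns Git2 deficiency, the recruitment of myeloid-derived suppressor cells to the intestine and necrotizing enterocolitis, an inflammatory bowel disease of newborns. The comparison asks which epithelial genes differ between the genotypes.

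Git2 encodes a scaffold protein that turns off Arf GTPases and binds PIX exchange factors and PAK kinases. It was measured at 22.2, 23.7 and 22.7 CPM in the wild-type libraries and at 17.4, 15.5 and 16.8 CPM in those labelled Git2-knockout. The means were 22.9 ± 0.76 and 16.6 ± 0.98 CPM (SD, n = 3 libraries each). Git2 fell by 0.47 on the log2 scale (SE 0.07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.44e-05). Its level was therefore still 72.3% of wild-type (95% interval 62.9% to 83.1%), a partial reduction. In TPM it was at 9.34, 9.84 and 9.33 in wild-type and 8.06, 7.58 and 7.97 in the other libraries, a smaller relative fall. A transcript can persist when a targeted gene makes no protein, and the altered part of the gene is not given in the sources used here, so this level does not check the genotype. Directions below are therefore those of the libraries labelled Git2-knockout. Its paralog Git1 was at 188 to 195 CPM in these libraries and at 190 to 200 CPM in wild-type.

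Connective tissue and vascular genes, Afp and a set of zinc finger genes were higher in the libraries labelled Git2-knockout, and lipid-handling and B cell genes were lower. Of 13558 genes tested, 4013 rose and 3712 fell by edgeR's quasi-likelihood test at an adjusted p of 0.05, 57% of the total. Most of these changes were small, with a median absolute log2 fold change of 0.36. At least 2-fold changes were seen in 631 genes, 500 upward and 131 downward, a number that was 196 with a filter of 5 CPM in 3 libraries and 220 for genes changed at least 2-fold on the log2(TPM + 1) scale. The values of the groups did not overlap in 62.9% of tested genes, where chance gives 10%. With limma-trend on log2(TPM + 1), 5372 genes rose and 1865 fell, and the median of all genes lay at 0.14 on the log2 scale, so that 74.2% of calls were upward against 51.9% of the edgeR calls. Fold changes also followed transcript length and GC content. With both trends removed edgeR called 3068 rises and 2767 falls, and 4126 of the 7725 original calls remained in the same direction.

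Among genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rises included Tuba1a, an alpha-tubulin (2.75), Bmp5, a bone morphogenetic protein (2.67), Camk4, a calcium-dependent kinase (2.57), Aff2 (2.47), the pericyte gene Rgs5 (2.16) and the basement membrane collagen Col4a5 (2.16), all as log2 fold changes. Zfp979 (6.36), Eno1b (6.11), Zfp990 (5.60) and Zfp982 (2.23) were also among them, and their reads can be shared with near-identical copies. Zfp979 went from 0.214 ± 0.107 CPM in wild-type to 18.1 ± 3.74 CPM (SD, n = 3 each). Among rises with the smallest p, Afp, the fetal plasma protein alpha-fetoprotein, went from 58.7 ± 3.28 to 253 ± 9.44 CPM, a log2 fold change of 2.11 (SE 0.05, edgeR, Benjamini-Hochberg adjusted p = 2.88e-14). Wdfy1 (1.73), the metalloproteinase Adamdec1 (1.81), the phosphate transporter Slc20a1 (1.20) and the mitochondrial transhydrogenase Nnt (1.32) followed.

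Under the same limits on expression and overlap, the largest falls were in Col16a1 (-3.57), Zg16, a goblet and acinar cell lectin (-3.41), the scramblase Ano6 (-3.07), the acyl-CoA thioesterase Acot12 (-2.48), and the fatty acid and bile acid binding proteins Fabp1 (-2.16) and Fabp6 (-2.43). Gstm3 (-1.80), Reg3g (-1.70), the B cell receptor component Cd79a (-1.59) and Lrrc26 (-1.53) completed these 10. Ano6 had the smallest p of all genes, from 176 ± 5.69 CPM in wild-type to 20.9 ± 1.42 CPM (SE 0.06, edgeR, Benjamini-Hochberg adjusted p = 1.44e-15). The zinc transporter Slc39a4 (-1.43) and the macrophage growth factor receptor Csf1r (-1.12) were the other falls with the smallest p.

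**Figure D1:**
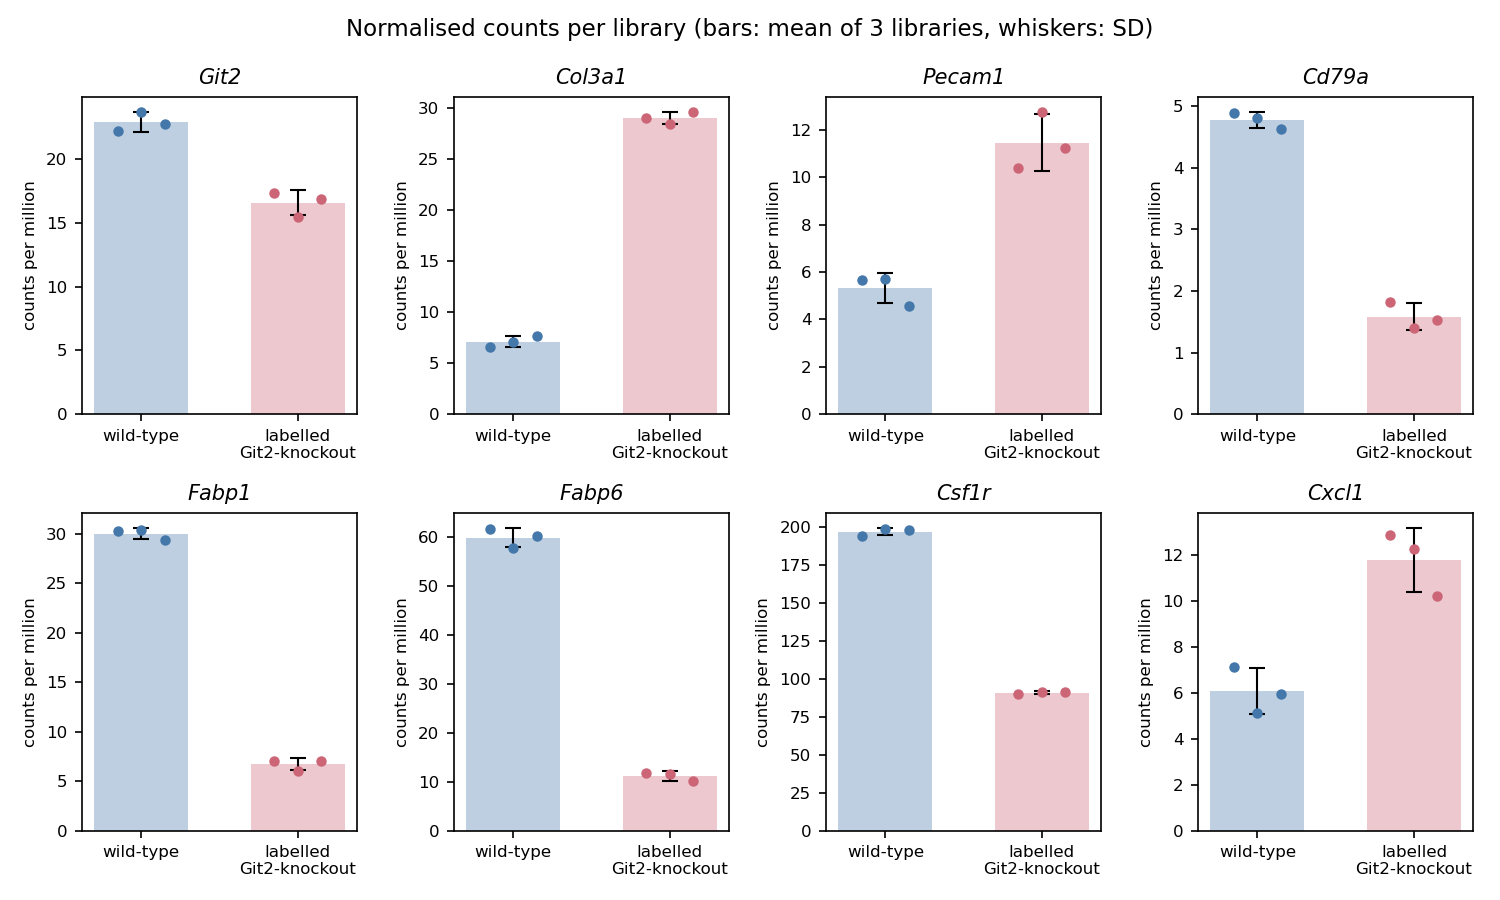
Normalised read counts (CPM) of 8 genes in each library (points), with bars at the mean of 3 libraries and whiskers for the SD, wild-type in blue and labelled Git2-knockout in red. Git2 remained at 72.3% of its wild-type level, Col3a1, Pecam1 and Cxcl1 were higher, and Cd79a, Fabp1, Fabp6 and Csf1r were lower in the libraries labelled Git2-knockout.

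Genes of fibroblasts, blood vessels and red blood cells were higher in the libraries labelled Git2-knockout, and B cell genes were lower. Of 17 tested genes of fibroblasts and smooth muscle, 15 rose and 0 fell (16 rose when adjusted over the list alone), with a median log2 fold change of 1.29. Col3a1 went from 7.13 ± 0.578 to 29.0 ± 0.601 CPM, Sparc from 13.7 ± 0.452 to 42.4 ± 1.55 CPM and Col1a2 from 4.51 ± 0.106 to 15.2 ± 0.638 CPM (SD, n = 3 each). In the endothelial list 15 of 16 genes rose, also when adjusted over the list alone, with a median of 1.14, among them Plvap (1.10), Kdr (1.52) and Pecam1 (1.11). Of 7 erythroid genes 5 rose, also when adjusted over the list alone, with a median of 1.42, and Hbb-bs rose from 9.68 ± 0.377 to 36.2 ± 1.90 CPM. In the B cell list 8 of 9 genes fell, also when adjusted over the list alone, with a median of -0.94, and Cd79a went from 4.78 ± 0.135 to 1.59 ± 0.213 CPM. Camera with its preset correlation and Benjamini-Hochberg adjustment called all 4 lists, at adjusted p = 5.78e-07, 3.08e-06, 0.023 and 7.42e-04. The calls were lost with an estimated correlation, at adjusted p = 0.158 with an estimated correlation for the fibroblast, endothelial and B cell lists and 0.274 for the erythroid list.

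The lists of other blood and nerve cell types were not called by camera. Of 17 macrophage genes 5 rose and 1 fell (4 and 1 when adjusted over the list alone), with a median of 0.22 (camera, Benjamini-Hochberg adjusted p = 0.351). After removal of the length trend 10 macrophage genes rose and 1 fell, with a median of 0.37 (camera adjusted p = 0.132), and with the length and GC trends both removed the median was 0.42 (0.0586). The complement genes C1qa (0.46) and C1qb (0.64) rose while Csf1r fell from 197 ± 2.49 to 90.7 ± 0.992 CPM. Of 9 neutrophil genes 2 rose, the matrix protease Mmp9 (1.94) and Il1r2 (1.33), also when adjusted over the list alone (camera adjusted p = 0.404). Of 6 T cell genes 2 rose, Ptprc (0.33) and Itgae (0.69), and Lck fell (-0.47), with 3 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.351). All 3 calls were lost when a single library was left out, with edgeR adjusted p = 0.0967 for Ptprc without wild-type replicate 3, 0.122 for Itgae without replicate 3 of the libraries labelled Git2-knockout and 0.162 for Lck without wild-type replicate 2. Ptprc lay at -0.03 with the GC trend removed. In the list of enteric neurons and glia, Ednrb rose (1.85) and the other 4 genes did not pass the test, also when adjusted over the list alone (camera adjusted p = 0.249).

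Absorptive and lipid-handling genes of the epithelium were lower in the libraries labelled Git2-knockout. Of 31 absorptive enterocyte genes 21 fell and 5 rose, also when adjusted over the list alone, with a median log2 fold change of -0.23. The apolipoproteins Apoa1 (-0.79), Apoc2 (-1.08) and Apoc3 (-1.12) fell, Apoa1 from 8057 ± 46.4 to 4659 ± 228 CPM (SD, n = 3 each). Of 25 genes of fatty acid oxidation and PPAR targets 15 fell and 4 rose, also when adjusted over the list alone, with a median of -0.19, and Acaa1b (-1.21) and Pdk4 (-0.75) fell. Camera with Benjamini-Hochberg adjustment called the absorptive list at adjusted p = 6.16e-04 and the fatty acid list at adjusted p = 0.0012, and both calls were lost, at adjusted p = 0.274 with an estimated correlation. These falls accompany the rise of fibroblast genes, whose median was 1.29 in the same libraries, and a link between them was not tested. Epithelial genes did not fall throughout. Of 27 tight and adherens junction genes 11 rose and 8 fell, with a median of 0.05.

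More markers fell than rose for both ends of the small intestine. Of 11 proximal genes 6 fell and 1 rose, also when adjusted over the list alone, with a median of -0.15, including Fabp1, the calcium-binding S100g (-0.87), Gata4 (-0.62) and Ces2a (-0.81). Of 11 distal genes 6 fell and 1 rose (6 and 2 when adjusted over the list alone), with a median of -0.31, including Fabp6, the bile acid-induced hormone Fgf15 (-0.91), and the bile acid exporter subunits Slc51a (-0.68) and Slc51b (-1.10). Fgf15 went from 336 ± 1.05 to 179 ± 5.68 CPM. Both lists passed camera at adjusted p = 0.0137 after Benjamini-Hochberg adjustment, and neither passed with an estimated correlation, at adjusted p = 0.274 with an estimated correlation for the proximal list and 0.301 for the distal list. With the length trend removed the proximal median was -0.23 (camera adjusted p = 0.00324) and the distal median -0.51 (0.0183). With the length and GC trends both removed they were -0.32 (9.11e-04) and -0.54 (0.00532). Of 25 genes of xenobiotic and oxidant defence 16 fell and 2 rose, also when adjusted over the list alone, with a median of -0.33 (camera adjusted p = 4.29e-04, adjusted p = 0.274 with an estimated correlation). Cyp2c55 (-3.08), Gstm3, Gstp1 (-0.88) and Gpx2 (-0.73) were among them. The fibroblast list had a median of 1.29 beside these falls too.

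Secretory cell genes went in different directions, in the same libraries in which the fibroblast list had a median of 1.29 and the endothelial list 1.14. Of 19 goblet cell genes 10 fell and 1 rose, also when adjusted over the list alone, with a median of -0.20, among them Clca1 (-0.66), Spink4 (-0.81) and Guca2a (-0.47), which lay at 0.05 with the length and GC trends both removed. Camera called this list (Benjamini-Hochberg adjusted p = 0.00105, adjusted p = 0.158 with an estimated correlation), and with the length trend removed its median was -0.06 (adjusted p = 0.0517) and with both trends removed -0.01 (0.276). Of 22 Paneth cell and antimicrobial genes 11 fell and 3 rose, also when adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.0429, 0.0636 without wild-type replicate 1, adjusted p = 0.391 with an estimated correlation). The call was lost with the length trend removed, with 7 rising and 4 falling and a median of 0.09 (camera adjusted p = 0.546). Reg3b fell from 97.2 ± 2.53 to 40.9 ± 2.92 CPM and Reg3g from 35.5 ± 0.266 to 10.9 ± 1.32 CPM, while Mptx2 rose (1.27) and Defa21 fell (-0.50), with Defa21 at 0.037 once the length trend was removed. Of 24 enteroendocrine genes 11 rose and 3 fell, also when adjusted over the list alone, with a median of 0.33, including neurotensin (Nts, 1.16), Neurod1 (0.96), Scg2 (0.92) and proglucagon (Gcg, 0.43). Their call (camera adjusted p = 0.0463) was lost, at adjusted p = 0.391 with an estimated correlation, and also without wild-type replicate 1 (camera adjusted p = 0.0713) or without replicate 1 of the libraries labelled Git2-knockout (0.144). With the length trend removed 16 enteroendocrine genes rose and 0 fell, with a median of 0.39 (camera adjusted p = 1.55e-04, and 1.57e-06 with both trends removed). Of 5 pancreatic acinar genes 4 fell, also when adjusted over the list alone, Zg16, Ctrb1 (-0.90), Cela1 (-0.82) and Clps (-0.42), though the median of -0.82 was called at camera adjusted p = 0.0144 and lost at adjusted p = 0.274 with an estimated correlation. With the length trend removed the acinar call was lost too (camera adjusted p = 0.171, and 0.163 with both trends removed), and Clps lay at 0.035.

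**Figure D2:**
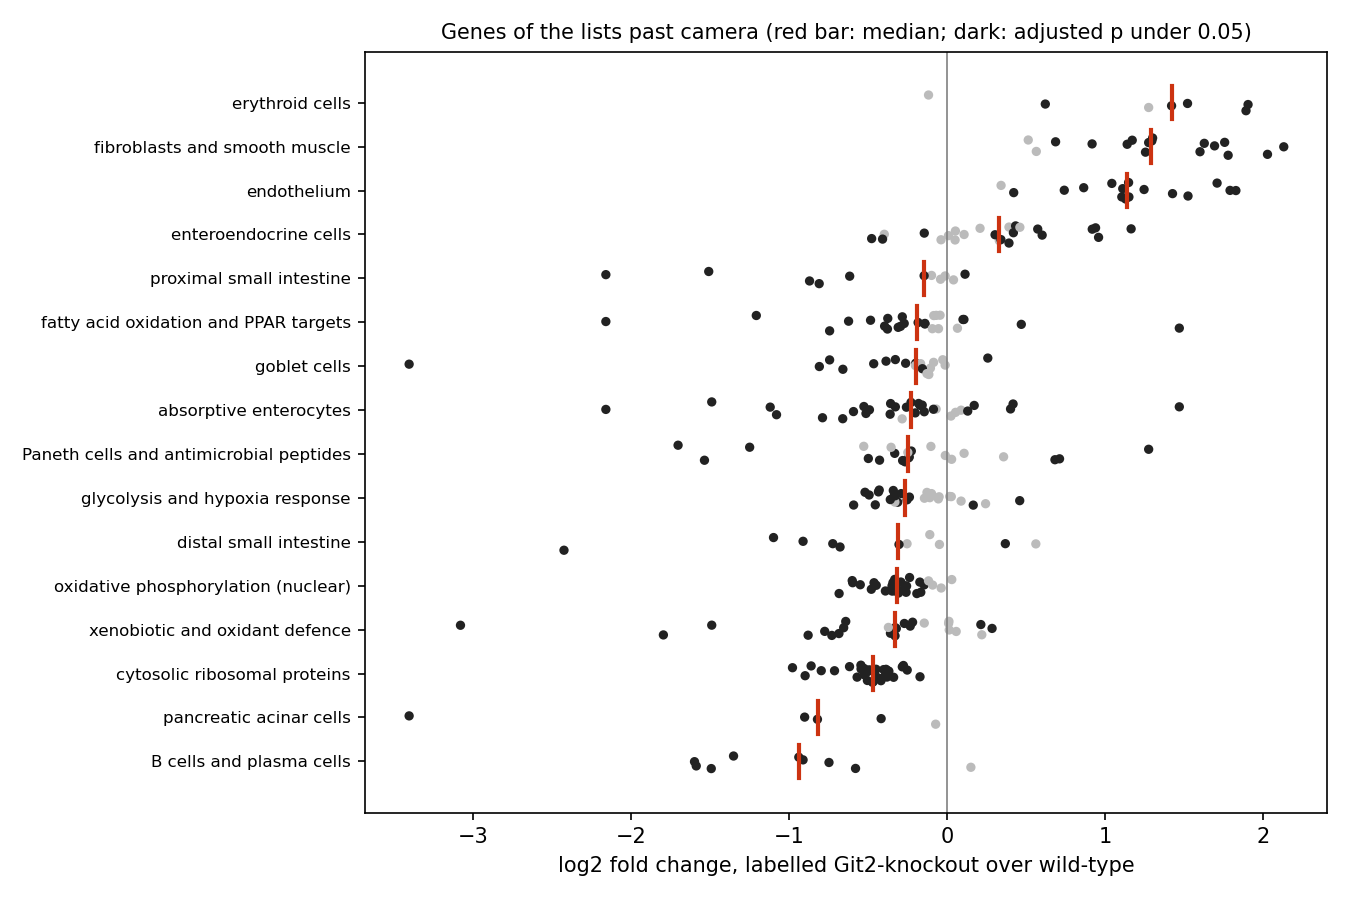
Log2 fold change (horizontal axis, labelled Git2-knockout over wild-type) of each tested gene of the 16 lists past camera, 1 point per gene, dark where the adjusted p passed the threshold and grey where it did not, with a red bar at the list's median. Medians run from -0.94 in B cell genes to 1.42 in erythroid genes.

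More stem cell and cell cycle genes fell than rose. Of 21 stem cell genes 10 fell and 2 rose, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0724). The stem cell list passed camera with the length trend removed (1 rose, 10 fell, median -0.24, adjusted p = 7.45e-04) and with the length and GC trends both removed (6.92e-04), and with no trend removed it stood at adjusted p = 0.391 with an estimated correlation. Lgr5, the receptor that marks crypt base stem cells, rose from 61.1 ± 2.13 to 85.2 ± 2.08 CPM (SD, n = 3 each), and Ascl2 (-0.86), Ephb3 (-0.58) and Cdca7 (-0.46) fell. Of 32 cell cycle genes 14 fell and 7 rose, also when adjusted over the list alone (camera adjusted p = 0.128, 0.132 with the length trend removed and 0.00732 with both trends removed, and with no trend removed adjusted p = 0.435 with an estimated correlation), and the replication licensing genes Mcm2 (-0.63), Mcm3 (-0.64) and Mcm5 (-0.68) fell. The fibroblast median of 1.29 and the endothelial median of 1.14 stood beside these falls.

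Factors that attract or feed myeloid cells changed individually in both directions. Of 30 such genes fixed beforehand 18 were expressed enough to test, 6 rose and 5 fell, also when adjusted over the list alone. The list's median was -0.05, its mean 0.08 and camera's direction downward (Benjamini-Hochberg adjusted p = 0.839). Cxcl1, a neutrophil chemokine, rose from 6.06 ± 0.991 to 11.8 ± 1.40 CPM, a log2 fold change of 0.96 (SE 0.13, edgeR, Benjamini-Hochberg adjusted p = 8.61e-06). Ccl25, the small-intestinal chemokine, fell by 0.43, Mif fell by 0.70 and Vegfa fell by 0.33 on the log2 scale. Cx3cl1, the most abundant of them, was at 278 ± 3.15 CPM in wild-type and 265 ± 10.6 CPM in the other group (log2 fold change -0.07, edgeR adjusted p = 0.149). Cxcl5, Ccl2, Csf2, Csf3, Il6, S100a8 and S100a9 were removed by the expression filter, with 0 to 12 estimated reads per library, so no difference in them was detectable at this depth.

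Innate signalling, junction and Git2 partner genes were mixed. Of 35 genes of Toll-like receptor and NF-kappaB signalling 10 rose and 7 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.702), with rises in Chuk (0.47), Cyld (0.38), Traf6 (0.38), Nfkbiz (0.32) and Tollip (0.12) and a fall in the inhibitor Nfkbia (-0.24). With the length and GC trends both removed, Cyld lay at -0.142 and Nfkbia at 0.014, and Tollip lost its call without replicate 3 of the libraries labelled Git2-knockout (edgeR adjusted p = 0.125). Of 27 tight and adherens junction genes 11 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.644). The claudins Cldn15 (-0.60) and Cldn3 (-0.49) fell, Cldn8 (0.54), Cldn4 (0.19), Tjp1 (0.46) and Ctnnb1 (0.16) rose, and Cdh1 was at 805 ± 3.68 and 855 ± 37.6 CPM (edgeR adjusted p = 0.0638). Of 22 GIT-PIX-PAK and focal adhesion genes 8 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.829), among them vinculin (Vcl, 0.46), Cdc42 (0.26) and Pak2 (0.27). With the GC trend removed Cdc42 lay at -0.084 and Pak2 at -0.065.

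Ribosomal protein and mitochondrial respiratory genes were lower, and fold changes followed transcript length. All 34 cytosolic ribosomal protein genes fell, also when adjusted over the list alone, with a median of -0.47, Rps14 from 514 ± 3.45 to 261 ± 9.84 CPM (SD, n = 3 each). Of 30 nuclear genes of oxidative phosphorylation 26 fell and 0 rose, also when adjusted over the list alone, with a median of -0.32, among them Ndufa2 (-0.69), Uqcrq (-0.60) and Cox5b (-0.55). Of 28 genes of glycolysis and the hypoxia response 15 fell and 2 rose (16 and 2 when adjusted over the list alone), with a median of -0.27, including Gapdh (-0.44), Tpi1 (-0.43) and Ddit4 (-0.49). Camera with Benjamini-Hochberg adjustment called the ribosomal, respiratory and glycolytic lists at adjusted p = 2.09e-12, 1.52e-07 and 0.0012. All 3 calls were lost, at adjusted p = 0.339, 0.323 and 0.323 with an estimated correlation. Across 12629 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.49 with transcript length and, across 13277 genes, of -0.48 with GC content. The median went from -0.30 in the shortest transcripts (157 to 1241 nt) to 0.29 in the longest (5540 to 30520 nt). With the length trend removed 20 ribosomal genes fell and 0 rose, with a median of -0.13. The ribosomal list still passed camera (adjusted p = 7.93e-05, and 5.8e-06 with the length and GC trends both removed). The glycolytic median was -0.22 with the length trend removed (camera adjusted p = 0.00324) and -0.14 with both removed (0.0139). The respiratory median was -0.03 with the length trend removed (camera adjusted p = 0.386). With the length and GC trends both removed the respiratory median was -0.09 and the list passed camera again (adjusted p = 0.00202).

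**Figure D3:**
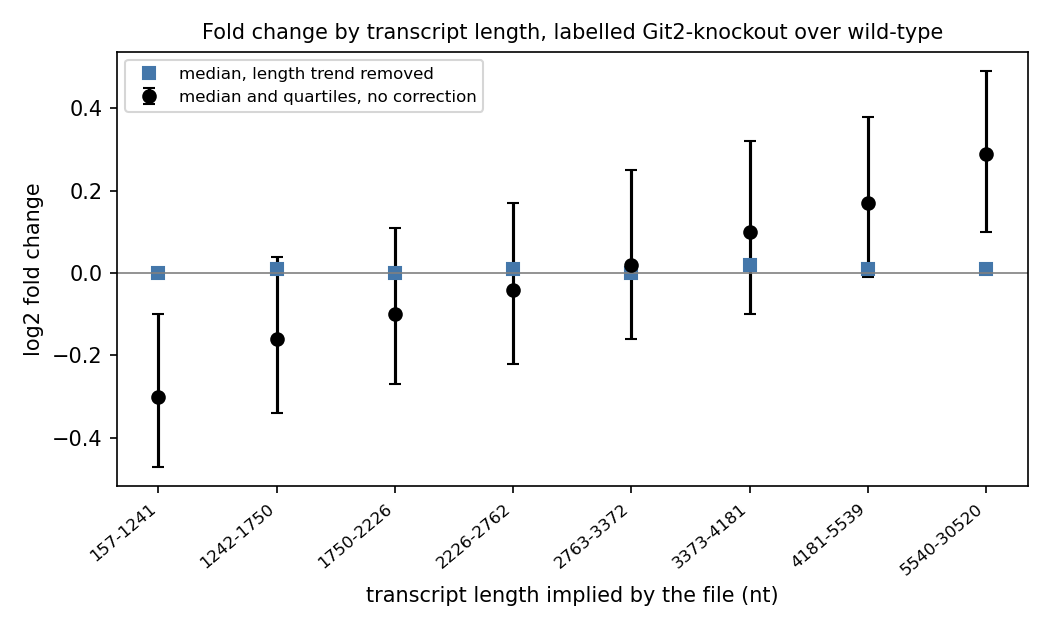
Median log2 fold change (vertical axis, labelled Git2-knockout over wild-type) in 8 groups of genes by transcript length in nucleotides (horizontal axis), with whiskers at the quartiles (black) and the median after removal of the length trend (blue). The medians go from -0.30 in the shortest group to 0.29 in the longest before removal.

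Genes close to Git2 on chromosome 5 did not change more often than others. Within 10 Mb of Git2, 110 of 222 tested genes (49.5%) were past the threshold, against 7583 of 13260 (57.2%) elsewhere, an odds ratio of 0.74 (95% interval 0.56 to 0.97, two-sided Fisher's exact test, p = 0.024). Neighbourhood was taken from the GRCm38 gene table. The lower share lost its call under several other settings, with an odds ratio of 0.97 when no expression filter was used.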

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

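Removal of the length and GC trends, the log2(TPM + 1) fit and the 1.5-fold test were chosen after seeing the data. Over 180 named genes, 3203 of 3374 recomputed values kept their direction and their side of the threshold. The numbers of genes that rose and fell ranged from 3430 to 4082 and from 3150 to 4261 when each library was left out in turn, and were 3222 and 3250 with DESeq2. Of the 7725 calls, 5509 remained in the same direction with the length trend removed, 4828 with the GC trend removed and 4126 with both. The genes changed at least 2-fold numbered 196 with the filter of 5 CPM in 3 libraries, which tests fewer genes, and 220 on the log2(TPM + 1) scale, where 1865 genes fell. A test of changes above 1.5-fold called 445 rises and 160 falls, because it asks for a larger change. Of the lists, 0 passed camera with an estimated correlation and 29 passed fry, which asks another question. Camera's p rose even for lists whose estimated correlation lay below the preset 0.01. For the goblet list (-0.031) the unadjusted camera p went from 2.21e-04 to 0.016. The loss of a call in this setting therefore does not show by itself that correlated genes had made the call.

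The odds ratio for genes within 10 Mb of Git2 was 0.766 with RLE factors, 0.827 with upper-quartile factors, 0.784 with DESeq2, 0.971 without a filter, 0.809 with the length trend removed, 0.989 with both trends removed, 0.719 within 5 Mb, and 0.668 to 0.847 when each library was left out. These lost the call, except without wild-type replicate 3, where the lowest of that range was reached. Within 20 Mb the call was kept, with an odds ratio of 0.70 (95% interval 0.55 to 0.88, Fisher's exact p = 0.002). With the replicate block the odds ratio was 0.847 and 3863 genes rose and 3578 fell, and same-numbered libraries had correlations of 0.041, -0.001 and 0.05, so the numbers were not taken to pair the samples.

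Some small changes reversed. With the length trend removed these were Defa21 (0.037), H2-D1 (0.02), H2-Q4 (0.005), Ret (-0.187), Clps (0.035) and the Paneth list (0.088). With the GC trend removed they were Cdc42 (-0.084), Pak2 (-0.065), Cx3cl1 (0.137), H2-Q4 (0.03) and Ptprc (-0.03). With both removed they were Pak2 (-0.183), Cx3cl1 (0.09), Cyld (-0.142), Nfkbia (0.014), Defa21 (0.005), Guca2a (0.05), H2-T23 (0.007), H2-D1 (0.057), H2-Q4 (0.095), Ptprc (-0.105), Clps (0.094), Kdm5d (-0.011) and the Paneth list (0.099). On the log2(TPM + 1) scale they were H2-D1 (0.037) and H2-Q4 (0.029). Apart from the cases where the construction is named, the cause was not tested. Depth limits genes of few reads, such as Il6 and S100a8.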

Other observations

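Among the tests of explanations here, those of the B cell list, the length and GC trends, the summed zinc finger reads, the genes near Git2 and the splits of the libraries were chosen only after the result, or values close to it, had been seen.

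Of 25 cholesterol synthesis genes 12 rose and 3 fell, also when adjusted over the list alone, with Hmgcs1 (0.69), Idi1 (0.78) and the sterol carrier Stard4 (0.58) rising (camera, Benjamini-Hochberg adjusted p = 0.0667). With the length and GC trends both removed the cholesterol list passed camera, with a median of 0.15 (adjusted p = 9.24e-04), and with no trend removed it stood at adjusted p = 0.323 with an estimated correlation. Of 35 interferon response genes 13 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.659), with rises of Irgm2 (0.90), Ifit2 (0.65) and Gbp7 (0.47) and a fall of Isg15 (-0.89). Of 18 MHC genes 5 fell (2 when adjusted over the list alone), H2-T23 (-0.29, and 0.007 with the length and GC trends both removed), Tap2 (-0.23), and H2-D1 (-0.12) and H2-Q4 (-0.13), which lay at 0.037 and 0.029 on the log2(TPM + 1) scale (camera adjusted p = 0.28). With the length trend removed 4 MHC genes rose and 1 fell, with a median of 0.05, and the median was 0.14 with both trends removed. Tap2 (edgeR adjusted p = 0.0531) and H2-D1 (0.119) lost their calls without wild-type replicate 3, and H2-Q4 (0.139) without replicate 3 of the libraries labelled Git2-knockout. Of 20 suckling-type enterocyte genes 8 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.839), with rises of the fetal-to-adult repressor Prdm1 (0.51) and Nox4 (0.59) and falls of Clec2h (-0.46) and the neonatal Fc receptor Fcgrt (-0.41). Of 10 adult-type genes 4 rose and 5 fell, also when adjusted over the list alone, with sucrase-isomaltase (Sis) rising from 12.8 ± 0.229 to 24.1 ± 1.88 CPM and Pck1 falling (-0.40). The adult-type median was 0.06 while camera's direction was downward (adjusted p = 0.959). Of 18 genes of regenerating or fetal-like epithelium 7 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.436), with Ptgs2 (2.14) and Wnt5a (1.05) rising and Krt7 (-0.73) and Krt19 (-0.65) falling. Fibroblast genes had a median of 1.29 in the same libraries.

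Of 10 tuft cell genes 2 rose, Ptgs1 (1.08) and Hpgds (0.54), and 2 fell, Sucnr1 (-1.39) and Pou2f3 (-1.38), also when adjusted over the list alone. Without wild-type replicate 2 the edgeR adjusted p was 0.128 for Pou2f3 and 0.0657 for Tnfsf13, and without replicate 2 of the libraries labelled Git2-knockout it was 0.0913 for Il7. The tuft median was 0.14 and the mean -0.06 (camera, Benjamini-Hochberg adjusted p = 0.791). Of 8 colon genes 2 rose and 1 fell, also when adjusted over the list alone, among them Cldn8 (0.54) and B4galnt2 (-0.22) (camera adjusted p = 0.702). Of 9 lymphoid chemoattractants and epithelial cytokines 3 rose and 2 fell, also when adjusted over the list alone, with Ccl21a (1.46) and Il7 (0.45) rising and Il18 (-0.63) and Tnfsf13 (-0.75) falling (camera adjusted p = 0.958). Of 25 immediate early and heat shock genes 8 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.721), with Egr2 (0.32) rising and Ier2 (-0.40), Hspa8 (-0.25) and Hsph1 (-0.41) falling. Of 26 genes of the unfolded protein and integrated stress response 12 fell and 5 rose, also when adjusted over the list alone, among them Phgdh (-0.80), Creld2 (-0.62), Sdf2l1 (-0.61) and Sel1l (0.35) (camera adjusted p = 0.145). Of 23 genes of apoptosis, necroptosis and p53 targets 9 rose and 6 fell (10 and 7 when adjusted over the list alone), among them Trp53inp1 (0.94), Ccng1 (0.57), Pmaip1 (0.50) and Bax (-0.56) (camera adjusted p = 0.818). The Y-linked genes Uty (0.87), Ddx3y (0.78) and Kdm5d (0.40) rose among 4 tested sex-linked genes, also when adjusted over the list alone. The other, Eif2s3y, did not pass. It had 800, 828 and 781 estimated reads in wild-type and 801, 784 and 741 in the libraries labelled Git2-knockout. With the length trend removed all 4 sex-linked genes rose. The median of 0.59 of the sex-linked list was 0.06, and Kdm5d lay at -0.011, with the length and GC trends both removed. Uty was at 25.3 ± 1.87 CPM in wild-type and 46.1 ± 3.52 CPM in the libraries labelled Git2-knockout (SD, n = 3 each).

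A hypothesis for the fibroblast, endothelial and erythroid rises is that the libraries labelled Git2-knockout held more connective and vascular tissue beside the epithelium. It was tested on 39 further fibroblast, pericyte and endothelial genes from a list written before their values were seen, of which 29 rose and 2 fell, with a median log2 fold change of 1.14 (95% bootstrap interval 0.94 to 1.51). The gene Rhoj had been seen when that list was written and was left out only after the median with it, 1.19 over 40 genes, was known. A general loss of epithelium that raised all other cell types alike is argued against by the B cell genes, whose median was -0.94 (95% interval -1.59 to -0.58), and a transcript length trend by the fibroblast and endothelial median of 1.27 once that trend was removed (95% interval 1.08 to 1.44). What stays open is whether such cells were present in differing amounts or the same cells changed their expression, and Col3a1 at 29.0 and Pecam1 at 11.5 CPM in the libraries labelled Git2-knockout are low beside epithelial genes such as Apoa1 at 4659 CPM. The titles speak of epithelial cells and the design text of enteroids grown from crypts, which bears on whether such tissue could be present.

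The falls of the short ribosomal and respiratory transcripts may in part reflect the length trend between the libraries. Random lists matched on transcript length and mean expression had a median of -0.30 for the respiratory list, whose own median of -0.32 stood at percentile 38.6 of 10000 such lists, although with the length and GC trends both removed that list kept a median of -0.09 (camera adjusted p = 0.00202). For the ribosomal list the matched median was -0.35 and the list's own -0.47 at percentile 0.19. These random lists were drawn gene by gene, while the ribosomal genes had an estimated correlation of 0.619, so this percentile overstates the evidence. With the length trend removed the ribosomal median was -0.13. Whether that exceeds the spread of so correlated a list was not tested. The GC trend as the whole cause is argued against by medians of -0.41 for ribosomal and -0.33 for respiratory genes with that trend removed. The length trend differed within a group as well, with a Spearman correlation of log-ratio and length of 0.15 in replicate 1 and 0.56 and 0.51 in replicates 2 and 3 of the libraries labelled Git2-knockout, so its origin in RNA quality or preparation stays open and no biological explanation was tested.

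Clustered zinc finger genes of chromosome 4 were among the largest rises, and 10 of the 12 tested within 3 Mb of Zfp979 rose with 0 falling. Reads moved only among the 15 genes with Zfp symbols in this window would leave their sum level. That sum rose from 148 ± 1.2 to 301 ± 31.8 CPM (SD, n = 3 each), a log2 ratio of 1.03. Unnamed gene models and copies elsewhere were not in the sum, so reads moved from those cannot be excluded. Sequence carried along with the targeted gene is argued against because Git2 lies on chromosome 5, and genes changed at least 2-fold were not more frequent within 10 Mb of it (odds ratio 0.68, 95% interval 0.27 to 1.43, Fisher's exact p = 0.415). A candidate explanation is a difference in genetic background between the groups, which predicts clustered changes elsewhere: outside this cluster 42 neighbouring pairs of unlike-named genes were both changed at least 2-fold, against 25.7 on average over 10000 permutations of positions (permutation p = 0.001). Neighbouring genes can also be expressed together for other reasons, such as shared cell type, and an effect of Git2 itself stays open, so this remains a hypothesis.

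The 6 libraries can be divided into equal groups in 10 ways, too few for a share below 0.1, and for each result below only 1 division, the real one, gave as large a value. The real division gave 4013 higher and 3712 lower genes, 631 genes changed at least 2-fold and 110 called genes within 10 Mb of Git2 by edgeR's quasi-likelihood test, and the highest of the other divisions gave 0 in each case. The other divisions mix the labels, which places the difference between the labelled groups inside each part and lowers the number of calls. With 0 genes called anywhere, their count near Git2 had to be 0 and says nothing about that region. For gene lists past camera the real division gave 16, and the others gave 4 to 9 although edgeR called 0 genes in each. Camera with the preset correlation thus called lists in every division. Each other division still sets more libraries of 1 label against more of the other, so part of the labelled difference remains in it. These calls therefore cannot tell how often camera calls a list wrongly, and no division free of that difference was available as a check on a single list call.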
